A study of Mus musculus with 8 samples.

How the data were processed

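RNA from the visual cortex of 8 male mice at postnatal day 17 was measured on Affymetrix Mouse Gene 1.0 ST arrays, 1 array per mouse. Per the labels, 4 mice were wild type (WT) and 4 carried MeCP2 S421A, a knock-in allele of the methyl-CpG-binding protein MeCP2 in which the serine S421 is replaced by alanine. The mice were littermates from 2 litters, and each litter gave 2 WT and 2 S421A animals. Animals are numbered here from 1 to 4 within each genotype in the order of the samples, and numbers 1 and 2 came from litter 1 and numbers 3 and 4 from litter 2. These numbers are not those of the sample titles, whose replicate numbers 1 and 2 match the litter. RNA was extracted with Trizol and cleaned on MinElute columns, and biotin-labelled cDNA was made from 100 ng of total RNA.

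The deposited values are log2 intensities, 1 per probe set and array, which the authors made with Affymetrix Expression Console 1.1 and RMA, per the submitters' processing notes. RMA corrects background, normalizes between arrays and summarises the probes of each set, and it compresses differences at low intensity. The values ran from 2.91 to 15.3 and the median over all 35556 probe sets lay between 7.08 and 7.12 in the 8 arrays. Whether any further scaling or centring followed RMA is unknown. No count stands behind an array value, so the number of arrays limits the precision. No genome build was stated, so no coordinates are given.

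Gene symbols came from a reference table of the probe sets' genes. It named 23410 of the probe sets, of which 21789 had 1 symbol and were tested, 1621 had several symbols and were left out, and a further 12146 had no name and entered only 1 alternative and a check of dim probe sets. The tested probe sets covered 19938 genes, and 999 of these had more than 1 probe set. Entrez identifiers of 21698 tested probe sets (99.6%) were found in the RefSeq gene table, and 0 symbols differed. Mecp2 and Cdkl5 were not among the tested probe sets and were not analysed here. No column belonged to another sample.

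The genotype comparison was a limma 3.58.1 fit (lmFit and eBayes, R 4.3.3) of S421A minus WT over all 8 mice. The litter comparison was litter 2 minus litter 1 with genotype as a covariate, and the interaction was the genotype difference in litter 2 minus that in litter 1. All tests were two-sided, with Benjamini-Hochberg adjustment over the 21789 probe sets and a threshold of 0.05. The genotype difference was also fitted within each litter. Litter was given by the labels, and it was added to the genotype fit as a block as an alternative. Its consensus correlation (statmod 1.5.0) was 0.0116, and the block ended no call and changed the number of probe sets past the threshold from 0 to 0. Single values were compared by exact permutation of the animals, for which 4 against 4 allows no p below 0.0286 and permutation within litters none below 0.0556.

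Gene lists were fixed before the data were examined, together with the tests, the rule for named genes and most alternatives. They covered MeCP2 cofactors, reported MeCP2 targets, genes flanking Mecp2, immediate early genes, late activity-induced genes, excitatory synapse, inhibitory synapse, interneuron markers, cortical layer markers, dendrite cytoskeleton, critical period plasticity and perineuronal nets, ion channels, long neuronal genes, glucocorticoid response, circadian clock, astrocytes, oligodendrocytes, oligodendrocyte precursors, microglia, vascular cells, meninges, choroid plexus, blood, hippocampus, thalamus and striatum, immature and cycling neurons, ribosomal proteins, oxidative phosphorylation, heat shock and protein folding stress, and replication-dependent histones. A further list of Y-linked genes and Xist was read as levels and not tested. Of 885 list entries 780 were measured, and some genes stood in more than 1 list. The 30 lists with at least 5 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. The same lists were tested with camera at a correlation estimated per list, with camera on ranks, and with fry, which asks whether a list's genes move on balance one way without comparing them with other genes. Beside each list called, its members were also counted after adjustment over the list alone. A list's median is the median log2 difference of its members, at 1 probe set per gene.

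The genes named are those of smallest p for genotype (10 in each direction), litter (10 in each direction) and interaction (5), the members of smallest p in each list, and a set chosen by name (Bdnf, Fos, Arc, Npas4, Egr1, Gad1, Pvalb, Sst, Crh, Fkbp5, Sgk1, Irak1, Igf1, Gfap, Mbp and Slc17a7). Genes outside this rule are marked as chosen after their values were seen. For genes with several probe sets the brightest was used.

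The genotype fit was tested on simulated data with the spread of these arrays, in 10 runs with 200 changed genes each. It recovered 2.4% of genes shifted by 0.25 on the log2 scale, 50.6% at 0.5, 84.6% at 0.75 and 94.6% at 1, with 61 false calls over the 10 runs. A list of 17 genes shifted by 0.25 was called in 10 of 10 runs, with 0 other lists. The simulated genes were drawn independently of each other. In the real genotype fit the estimated correlation between list members had a median of 0.12 and was 0.49 for the hippocampus list. The runs therefore do not measure how often lists are falsely called in these data.

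The alternatives were a further quantile normalization, centring each array on its median, array weights, leaving out the dimmer probe sets (those below the median level), 1 probe set per gene, every probe set, an intensity trend with a robust prior, an adjusted p of 0.1, litter as a fixed or random block, omission of genotype from the litter fit, and leaving out each animal in turn. Omitting both animals numbered 4, using the hippocampus list as a covariate, testing lists on the interaction term, and combining the litter block with an estimated correlation were chosen after the data had been seen. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.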

Results

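Gene expression was profiled in the visual cortex of 8 male mice at postnatal day 17. The mice were 4 WT and 4 MeCP2 S421A littermates, with 2 of each genotype in each of 2 litters. MeCP2 binds methylated DNA and is mutated in Rett syndrome, and S421 is a site phosphorylated upon neuronal activity. The comparison of genotypes asks how cortical mRNA levels differ when this site cannot be phosphorylated. Every pair of arrays correlated at 0.989 to 0.997 over the tested probe sets. The lowest mean correlations with the other arrays, 0.992 each, were those of WT 4 and S421A 4, both from litter 2. The neuronal transcript Slc17a7, which encodes the vesicular glutamate transporter of cortical excitatory neurons, measured 12.89 ± 0.06 (log2, SD, n = 4) in WT and 12.89 ± 0.06 in S421A. Of the Y-linked genes Eif2s3y measured 9.79 on average, Uty 8.99 and Kdm5d 8.22, against 4.80 for Xist, the transcript of the inactive X chromosome, in these males.

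**Figure D1:**
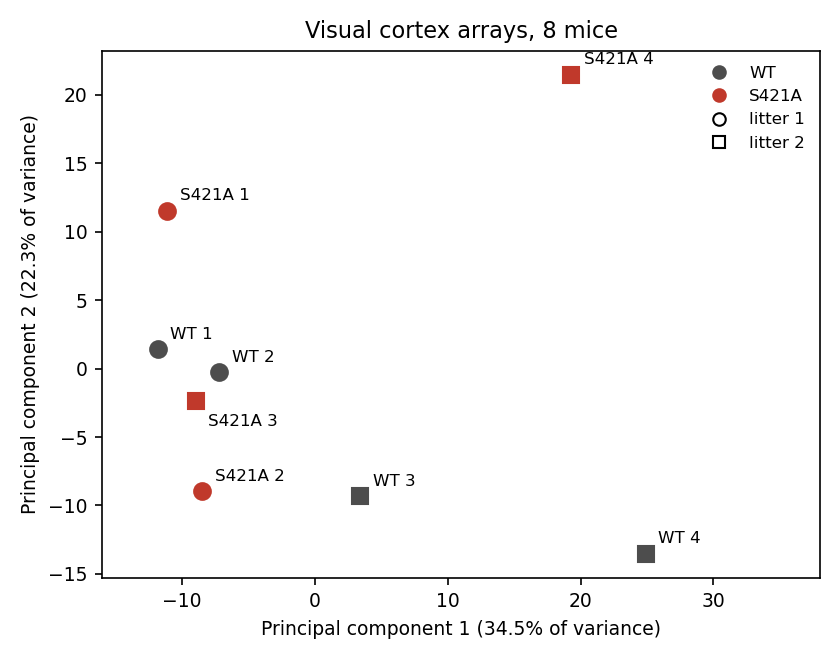
Principal components of the 8 arrays over the tested probe sets, with component 1 (34.5% of the variance) on the horizontal axis and component 2 (22.3%) on the vertical axis, colour for genotype and marker shape for litter. WT 4 and S421A 4 lie at the right, at 24.9 and 19.3 on component 1, and the other 6 arrays lie between −11.8 and 3.39.

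Neither the genotypes (exact two-sided permutation p = 0.571) nor the litters (exact p = 0.0857) passed the threshold on component 1.

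No single gene passed the test between S421A and WT cortex. Among the genes with the smallest p, Neurod6, a transcription factor of cortical pyramidal neurons, measured 9.99 ± 0.21 in WT and 9.52 ± 0.20 in S421A (SD, n = 4 each), a difference of −0.47. Pls3, which encodes an actin-bundling protein, measured 10.63 ± 0.26 and 10.13 ± 0.18, a difference of −0.50. The cytoplasmic RNA sensor gene Ddx58 differed by −0.40, Palmd by −0.27 and Rapgef6, an exchange factor for Rap GTPases, by −0.34. The genes of smallest p in the other direction were dim, with values near 4 to 7. They included the olfactory receptor genes Olfr60 (0.48), Olfr344 (0.57), Olfr1290 (0.49) and Olfr996 (0.41), the natural killer cell receptor gene Klrc3 (0.36), Tex22 (0.46), 1700031F05Rik (0.85) and Gch1 (0.48), which encodes the first enzyme of tetrahydrobiopterin synthesis. The others among the 10 of smallest p in each direction were Dsg1c (0.39) and E030011O05Rik (0.29), and Zfy1 (−0.32), R3hdml (−0.34), Dnah7a (−0.36), Trim30d (−0.43) and 4930555K19Rik (−0.42). The SE of these differences lay between 0.07 and 0.18, and the adjusted p of each was 1.00 in the limma fit.

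None of the measured genes tied to MeCP2 in earlier work passed the test between the genotypes. Bdnf, the neurotrophin gene regulated by activity and by MeCP2, measured 7.88 ± 0.05 in WT and 7.74 ± 0.09 in S421A (SD, n = 4 each). Of the 30 reported MeCP2 targets measured, 11 were higher and 19 lower in S421A (median −0.03), with Id3 at −0.25, Crh at −0.17, Fkbp5 at 0.03, Sgk1 at −0.01 and Irak1 at −0.04. Of the 25 entries for MeCP2 cofactors 20 were measured, without Mecp2, Cdkl5, Ncor1, Ncor2 and Foxg1. Those measured had a median of −0.04, and the histone deacetylase gene Hdac2 differed by −0.15. Genes flanking Mecp2 on the X chromosome had a median of −0.00345, and the smallest p among them was that of the kinase gene Pnck (0.25). The activity-induced genes Fos (0.07), Arc (0.14), Egr1 (0.13) and Npas4 (−0.06) had SEs of 0.13 to 0.19 and did not pass. Immediate early genes as a list had a median of 0.06, with the matricellular gene Ccn1 at −0.31, and late activity-induced genes one of −0.02, with the granin gene Scg2 at −0.21.

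Synaptic and neuronal lists lay close to 0. The median was −0.03 for the excitatory synapse (Homer3 −0.24), −0.04 for the inhibitory synapse (Gad1 −0.04; the GABA-A receptor subunit gene Gabra5 −0.36), −0.03 for interneuron markers (Pvalb −0.08, Sst −0.07, Calb2 −0.30) and 0.03 for cortical layer markers (Otof 0.21). Dendrite cytoskeleton genes had a median of −0.04 (the neurofilament gene Nefh −0.15), plasticity and perineuronal net genes one of −0.02 (the protease gene Mmp9 0.21, the growth factor gene Igf1 −0.10), ion channels one of −0.0057 (Kcnj3 −0.18) and long neuronal genes one of −0.02 (Robo1 −0.17). Immature and cycling neuron markers had a median of 0.01 (Cdk1 0.21) and replication-dependent histones one of 0.04 (H4c3 0.29).

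Non-neuronal lists had medians of −0.08 for oligodendrocytes (16 of 21 members lower; Aspa −0.24, Mbp −0.05), −0.05 for astrocytes (18 of 23 lower; Id4 −0.19, Gfap −0.22) and −0.07 for vascular cells (20 of 24 lower; Abcb1a −0.15). Microglia had a median of −0.04 (Ly86 −0.25), oligodendrocyte precursors −0.04 (Bcas1 −0.16), meninges 0.03 (Ptgds 0.19), choroid plexus 0.03 (Steap1 0.17), blood −0.01 (Car1 0.21), and thalamus and striatum −0.04. The glucocorticoid response list had a median of −0.01 (Mt1 −0.18), the circadian clock 0.02 (Bhlhe41 −0.20), ribosomal proteins 0.03 (Rplp2 0.26), oxidative phosphorylation 0.02 (Uqcrh −0.13), and heat shock and protein folding stress 0.0022 (Dnajb5 0.10). None of these lists passed in the fit without litter and with all animals. However, several passed with 1 animal or the dimmer probe sets left out, among them oligodendrocytes without S421A 3 (−0.15, adjusted p = 1.76 × 10⁻⁵) and ribosomal proteins without S421A 4 (0.10, adjusted p = 0.00234). Over all animals with an estimated correlation the adjusted p was 0.862 for oligodendrocytes and 0.880 for ribosomal proteins. With litter as a block oligodendrocytes (adjusted p = 0.00917) and astrocytes (adjusted p = 0.0364) passed as lower in S421A, both at adjusted p = 0.904 with an estimated correlation, and on ranks oligodendrocytes, astrocytes and vascular cells passed (adjusted p = 0.0421 each; adjusted p = 0.862 each with an estimated correlation). The median, the mean and the direction of the test did not share a sign for the Mecp2-flanking genes, blood, the stress list, cortical layer markers and immature neuron markers.

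Hippocampal markers were the exception: as a list they were lower in S421A, with 15 of 17 members lower and a median difference of −0.26 (camera adjusted p = 0.000173). The call was lost with the list's own correlation (adjusted p = 0.862 with an estimated correlation), and 0 of the 17 members passed, whether over all probe sets or adjusted over the list alone. Tgfb2 differed by −0.25, C1ql3 by −0.26 and Fibcd1 by −0.32. The animals' means over the list were 8.16 ± 0.29 in WT and 7.92 ± 0.32 in S421A (SD, n = 4 each; exact two-sided permutation p = 0.257). The difference was −0.30 in litter 1 and −0.19 in litter 2, and it was uneven between animals. In litter 1 WT 1 had 8.15 and WT 2 7.76, against 7.68 for S421A 1 and 7.62 for S421A 2. In litter 2 WT 3 and S421A 3 both had 8.30, WT 4 had 8.44 and S421A 4 had 8.06. Exact permutation within litters gave p = 0.0556, the smallest it can give, and the astrocyte list gave the same. These markers also differed between the litters, by 0.47 on the same measure. Without S421A 2 the median was −0.18 and the call was lost (adjusted p = 0.147; range 1.26e-09 to 0.904 over the alternatives). The median itself ran from −0.41 to −0.16 over the alternatives. The call was also lost with array weights (median −0.19, adjusted p = 0.133) and without the dimmer probe sets (median −0.26, adjusted p = 0.0613).

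Of 21789 probe sets, 0 passed the threshold for genotype in limma and 644 had an unadjusted p under 0.05 (365 higher and 279 lower in S421A), where p values spread evenly would give 1089. With litter as a block 0 passed and 829 had an unadjusted p under 0.05, and within litter 1 and litter 2 alone the counts were 0 (744 unadjusted) and 0 (1074 unadjusted). For the lists the count was 1 of 30 with camera, 4 on ranks, 0 with an estimated correlation and 0 with fry. With litter as a block it was 3, adding oligodendrocytes and astrocytes. The list count was 0 without S421A 2. It was 5 without WT 2 (adding immediate early genes as higher, and astrocytes, oligodendrocytes and vascular cells as lower). It was 6 without S421A 3 (adding astrocytes, oligodendrocytes, their precursors, microglia and vascular cells, all lower). It was 4 without S421A 4 (adding oligodendrocytes as lower, and ribosomal proteins and oxidative phosphorylation as higher) and 2 without WT 4 (adding oligodendrocytes as lower). The median SE of a genotype difference was 0.10, and for 97.7% of probe sets the 95% confidence interval excluded a change of more than 1.5-fold in either direction, but for only 37.0% one of more than 1.2-fold. The largest difference, chosen after its values were seen, was that of the neuropeptide gene Nts, which measured 7.58 ± 0.57 in WT and 6.57 ± 0.94 in S421A (SD, n = 4 each; SE of the difference 0.40) and did not pass. Across genes, the difference in litter 1 and that in litter 2 correlated at −0.03, and genes are not independent replicates.

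Between the litters 2 genes passed the test, and both were higher in litter 2. Only 2 litters were compared, so any separate handling of the 2 sets of littermates cannot be told apart from litter. Slc17a6, which encodes the second vesicular glutamate transporter, rose 1.76-fold from litter 1 to litter 2 (probe set 10553501, 9.04 ± 0.20 to 9.85 ± 0.20, SD, n = 4 each). The zinc-finger gene Tshz2 rose 1.78-fold on the dimmer of its probe sets (7.30 ± 0.41 to 8.13 ± 0.30), and its brighter one differed by 0.77 without passing. For both genes all 4 animals of litter 2 lay above all 4 of litter 1. Next in rank, at adjusted p of 0.0696 to 0.0714 and so not past the threshold, stood Gpr161, a receptor of the primary cilium (0.83), Man1a (0.60), Gpr101 (0.78), Vwc2l (0.65), the transcription factor gene Zbtb20 (0.98), Aspn (0.54), Ndst4 (1.47), the protease inhibitor gene Serpina3n (0.84) and the cation channel gene Trpc6 (0.58). In the other direction the smallest p values belonged to Alas2, which encodes the erythroid enzyme of haem synthesis (−0.62), the clock gene Ciart (−0.48) and the transferrin receptor gene Tfrc (−0.62). Efna5 (−0.45), Prr23a1 (−0.46), Prss56 (−0.48), Hspb2 (−0.52), Kcnh5 (−0.44), 1190005I06Rik (−0.56) and Olfr316 (−0.41) followed.

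**Figure D2:**
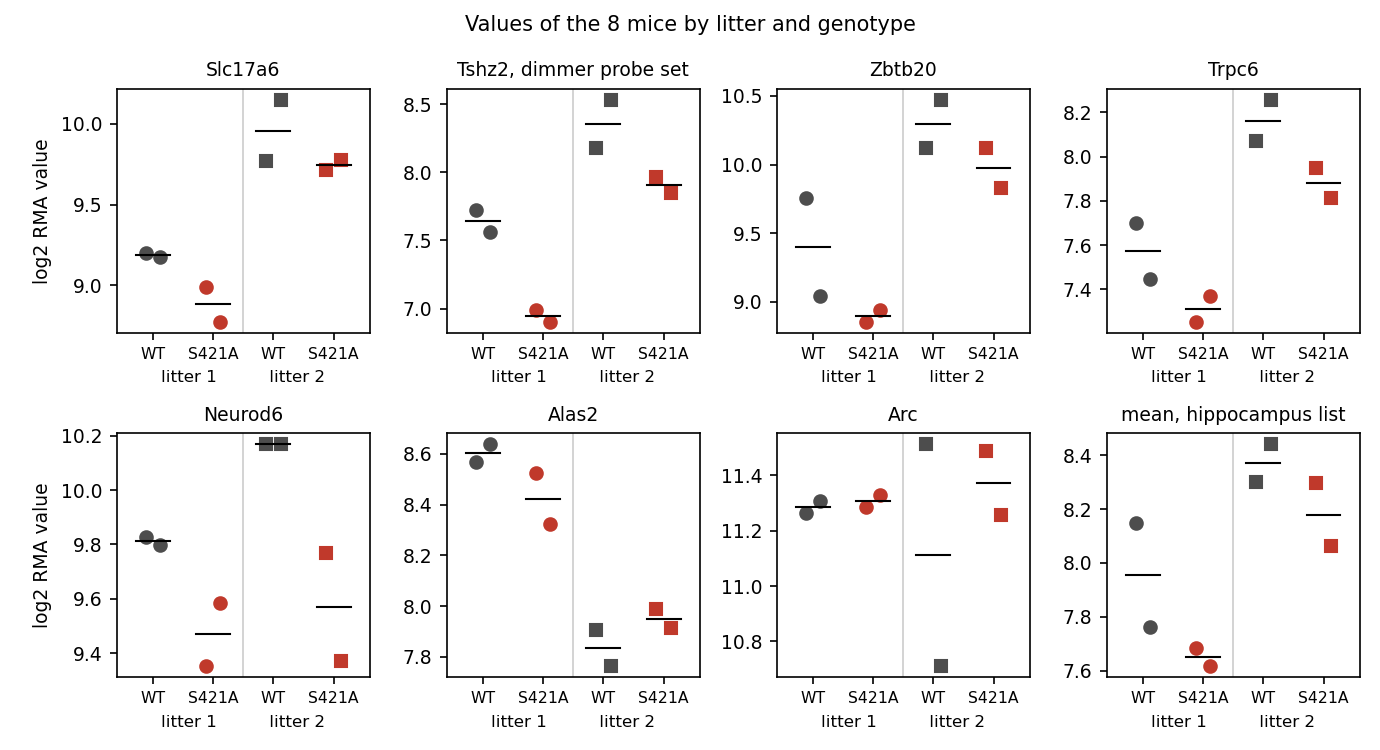
Log2 RMA values of each of the 8 mice for 7 genes and for the mean over the hippocampus list, by litter and genotype, with 1 point per mouse and a line at the mean of 2 mice. Slc17a6 and Tshz2 lie higher in litter 2 in both genotypes, and Alas2 lies lower there, by 0.62 without passing the test.

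Hippocampal markers rose as a list in litter 2, with 15 of 17 members higher and a median of 0.46 (camera adjusted p = 7.56e-13, or 0.342 with an estimated correlation). The animals' means over the list were 7.80 ± 0.24 in litter 1 and 8.27 ± 0.16 in litter 2 (SD, n = 4 each). Exact two-sided permutation of these means gave p = 0.0571 (0.171 adjusted over the lists). The litters overlapped, as WT 1 (8.15) lay above S421A 4 (8.06). Adjusted over the list alone 12 members passed, among them Zbtb20, Trpc6 and Tdo2 (0.80), and over all probe sets 0 did. Oligodendrocyte markers rose by a median of 0.21 (adjusted p = 2.64e-06; adjusted p = 0.342 with an estimated correlation), with 9 of 21 past the threshold adjusted over the list alone, such as the receptor gene Gpr37 (0.60), the galactolipid enzyme gene Ugt8a (0.43) and transferrin, Trf (0.39). Astrocyte markers rose by a median of 0.10 (adjusted p = 0.000601; adjusted p = 0.370 with an estimated correlation), and adjusted over the list alone the water channel gene Aqp4 (0.58) and the filament gene Gfap (0.45) passed, while Slc4a4 differed by 0.28 without passing. Vascular markers had a median of 0.09 (adjusted p = 0.0256; adjusted p = 0.547 with an estimated correlation) and 0 members adjusted over the list alone, with Ocln at 0.38, Slc2a1 at 0.26 and Vtn at 0.22. In the stress list (median 0.04, adjusted p = 0.0226; adjusted p = 0.423 with an estimated correlation) the 3 members that rose adjusted over the list alone, Hspa5 (0.42), Pdia6 (0.32) and Pdia4 (0.32), encode chaperones of the endoplasmic reticulum and not cytosolic heat shock proteins.

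The lists that fell in litter 2 were blood, ribosomal proteins, oxidative phosphorylation, cortical layer markers and immediate early genes. The last 4 of these moved with the arrays that stood apart: S421A 4 and WT 4 had means of 10.42 and 10.43 over the ribosomal list, where the other 6 animals had 10.63 to 10.73, and of 10.58 each over the oxidative phosphorylation list, where the others had 10.74 to 10.78. Without both animals the median was −0.0053 for ribosomal proteins, 0.0036 for oxidative phosphorylation, −0.05 for cortical layer markers and −0.01 for immediate early genes, and none of these 4 lists passed. For blood the median was −0.17 (adjusted p = 0.0060; adjusted p = 0.342 with an estimated correlation), and Alas2, the anion exchanger gene Slc4a1 (−0.38) and the haem synthesis gene Fech (−0.31) fell, adjusted over the list alone. On ranks the blood list did not pass (adjusted p = 0.0652). Only 6 of its 15 entries were measured, with no haemoglobin gene among them. Ribosomal protein genes had a median of −0.14 (adjusted p = 0.000601; adjusted p = 0.547 with an estimated correlation), with Rpl7a at −0.27, Rpl26 at −0.50 and Rps20 at −0.30, and oxidative phosphorylation genes one of −0.08 (adjusted p = 0.00723; adjusted p = 0.547 with an estimated correlation), with Uqcrq at −0.44, Ndufs5 at −0.48 and Ndufa7 at −0.36. Adjusted over the list alone, 0 members of either passed. Among cortical layer markers (median −0.12, adjusted p = 0.0226; adjusted p = 0.547 with an estimated correlation) Nr4a2 (0.53) and Lmo3 (0.34) rose adjusted over the list alone and 5 fell, which were Foxp1 (−0.39) and, chosen after their values were seen, Rprm, Syt6, Lmo4 and Cux2. Immediate early genes had a median of −0.17 (adjusted p = 0.0388; adjusted p = 0.703 with an estimated correlation), but the only member past the threshold adjusted over the list alone was Nr4a2, which rose, and Junb was at −0.42 and Jun at 0.32.

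**Figure D3:**
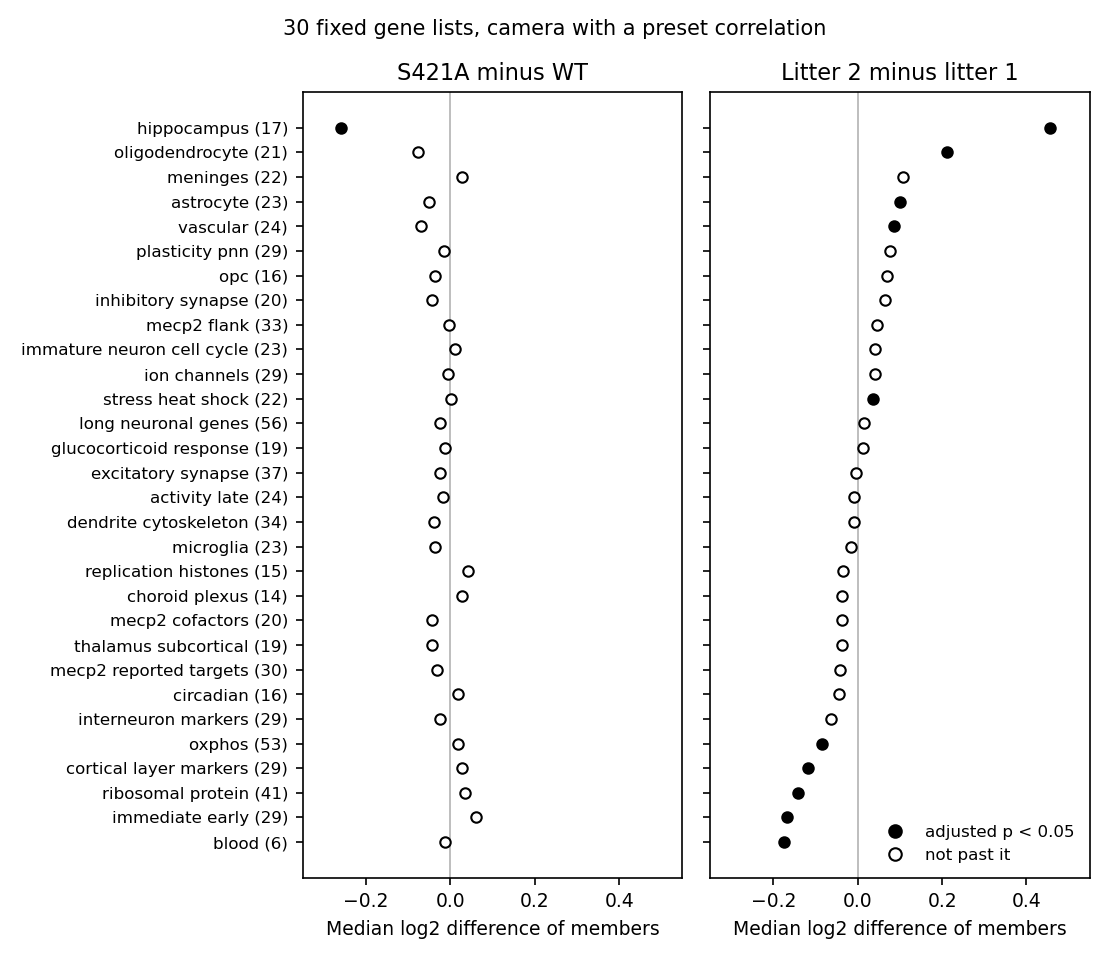
Median log2 difference of the members of each of the 30 gene lists, S421A minus WT on the left and litter 2 minus litter 1 on the right, with the number of measured members in brackets and filled points for lists past the threshold with camera at its preset correlation. The hippocampus list is the lowest on the left (−0.26) and the highest on the right (0.46); no list passes in either panel with an estimated correlation.

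The other 20 lists did not pass for litter. Their medians were 0.11 for meninges, 0.07 for oligodendrocyte precursors, −0.06 for interneuron markers, −0.01 for microglia, 0.06 for the inhibitory synapse, −0.04 for thalamus and striatum, −0.04 for the circadian clock, 0.08 for plasticity genes, −0.04 for MeCP2 cofactors, −0.04 for reported MeCP2 targets and 0.05 for the Mecp2-flanking genes. The remaining medians were 0.04 for ion channels, 0.04 for immature neurons, −0.04 for histones, −0.0091 for dendrite cytoskeleton, 0.01 for the glucocorticoid response, 0.01 for long neuronal genes, −0.0037 for the excitatory synapse, −0.04 for choroid plexus and −0.0085 for late activity-induced genes. The mean or the direction of the test had another sign than the median for microglia, the excitatory synapse and choroid plexus. Oligodendrocyte precursors passed as higher with array weights (0.10, adjusted p = 0.0226), without S421A 4 (0.11, adjusted p = 0.0131), without WT 4 (0.06, adjusted p = 0.0334) and without both animals numbered 4 (0.11, adjusted p = 0.000717). Meninges passed as higher with array weights (0.11, adjusted p = 0.0137), without S421A 2 (adjusted p = 0.0137), without S421A 3 (adjusted p = 0.0493) and without the genotype term (adjusted p = 0.0456). Interneuron markers passed as lower without S421A 3 (−0.12, adjusted p = 0.0227), and the glucocorticoid response as higher without both animals numbered 4 (0.11, adjusted p = 0.00993). Over all animals with an estimated correlation the adjusted p was 0.423 for oligodendrocyte precursors and 0.547 for meninges. It was 0.598 for interneuron markers and 0.814 for the glucocorticoid response. For microglia the test already pointed up, and only the median changed sign. The list passed as higher with array weights (median 0.10, adjusted p = 0.0226), without S421A 4 (0.061, adjusted p = 0.00504) and without both animals numbered 4 (0.12, adjusted p = 0.000369), with an adjusted p of up to 0.547 over the alternatives.

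For litter, 2 of 21789 probe sets passed in limma (adjusted p = 0.0419 for each), 39 had an adjusted p under 0.1 (36 higher and 3 lower in litter 2) and 2314 an unadjusted p under 0.05. The count of 2 fell to 0 without S421A 1, S421A 2, WT 2, S421A 4 or WT 4 and was 26 without WT 1, while the log2 difference of Slc17a6 stayed between 0.70 and 0.90 and its adjusted p between 0.0155 and 0.355 over the alternatives. Without S421A 3 the count was 2, but Slc17a6 and Tshz2 each had an adjusted p of 0.0600. Of the 30 lists 10 passed with camera, 8 on ranks (without blood, at adjusted p = 0.0652, and the stress list, at 0.0725), 0 with an estimated correlation and 0 with fry (smallest adjusted p = 0.0798). The mixed form of fry lets members move in either direction and likewise makes no comparison with other genes. In that form 18 lists passed for litter and 0 for genotype. The ribosomal list was lost without S421A 4 (adjusted p = 0.0581), oxidative phosphorylation without S421A 4 (0.137) or WT 4 (0.0931), cortical layers without S421A 2 (0.160) or S421A 4 (0.137), and immediate early genes without S421A 2 (0.132), WT 2 (0.233), S421A 4 (0.166) or WT 4 (0.932). The vascular list was lost without WT 2 (adjusted p = 0.110), S421A 3 (0.114) or WT 4 (0.0931), and the stress list without WT 2 (0.0526) or WT 3 (0.183), whereas hippocampal, oligodendrocyte, astrocyte and blood lists passed without each animal in turn at the preset correlation. Over the alternatives the adjusted p reached 0.887 for ribosomal proteins, 0.918 for oxidative phosphorylation, 0.932 for immediate early genes, 0.547 for cortical layers and vascular cells, and 0.423 for the stress list.

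No single probe set was called for a genotype difference that differed between the litters. With 2 animals per genotype in each litter, the median SE of this term was 0.19, so smaller differences could be missed. In the limma interaction term 0 passed (smallest adjusted p = 0.588) and 1004 had an unadjusted p under 0.05. The smallest p was that of the olfactory receptor gene Olfr243, whose S421A minus WT difference was −0.27 in litter 1 and 0.89 in litter 2 (difference 1.16, SE 0.16). Nhsl2 (0.82), Zfp944 (−0.73), Nxpe2 (0.68) and 4930591A17Rik (0.86) followed, with an adjusted p of 0.923 each.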

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

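In this part the array-scale tests of the hippocampal markers, the tests of tissue that shifts all such markers alike, the exact test by genotype, the lists on the interaction term and the omission of both animals numbered 4 were chosen after the results had been seen. Hippocampal markers were higher in litter 2 by a median of 0.46. Lists of 17 probe sets drawn at random at the same mean level had medians between −0.08 and 0.07 in 95% of 10000 draws, and the marker list lay at their percentile 100, which argues against a shift of array scale. The 18 further hippocampal markers in no list lay at percentile 52.91, which met the bound set beforehand against hippocampal tissue in the dissected piece. Their median of 0.0055 (SD 0.24) lay below that of the list by more than their SD. That comparison decides little about hippocampal tissue, because the list's own members ran from −0.07 to 1.32 and so did not shift alike. The further markers also had a median level of 8.31 in litter 1, against 7.64 over the tested probe sets, and 12 of the 18 lay above the latter. Tissue that shifts markers unequally stays open, and the bound was too wide for it. No hippocampal sample gives the shift each marker needs, and 4 of the 17 members of the list itself lay within 1 SE of 0 (Cpne4 −0.07, Lefty1 0.01). The further markers went both ways (Dock10 0.50, Sema5a 0.61, Npnt −0.27, Coch −0.25). The lists for thalamus and striatum (median −0.04) and choroid plexus (−0.04) did not pass for litter. Meninges (0.11) did not pass either, but did with array weights, without S421A 2, without S421A 3 and without the genotype term. These values do not exclude such tissue. A difference between the litters in development or rearing stays open as untested. The replicate numbers of the sample titles match the litter, so separate handling of the litters cannot be told apart from litter.

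Over the splits of the animals, the 2 probe sets past the threshold for litter were matched by 1 of 34 splits, the real one (highest other 0). That met the bound set beforehand against chance. However, 1 of 34 is the smallest share this test can give, and many of the splits part the genotypes unevenly, unlike the litters. Without the genotype term the litters gave 0 and another split gave 1. The count was also 0 without any of 5 single animals (S421A 1, S421A 2, WT 2, S421A 4 and WT 4). In addition, 4 of the 34 splits, the litters' own among them, had as many probe sets at an unadjusted p under 0.05. Chance can therefore not be excluded for the count of 2. At an adjusted p under 0.1 the litters gave 39 probe sets and the highest other split 1, a comparison with the same limits. The 10 lists were matched by 5 of 34, the litters' own split again among them (highest other 12), so chance cannot be excluded for the lists.

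Hippocampal markers were lower in S421A by a median of −0.26, at percentile 0 of the random lists, which argues against array scale. The same 18 further markers lay at percentile 44.87, which met the bound set beforehand. Their median of −0.017 (SD 0.15) lay short of that of the list by more than their SD. That comparison again decides little, because the list's own members ran from −0.50 to 0.03. Tissue that shifts markers unequally stays open for the reasons given for the litters, with 5 of the 17 list members within 1 SE of 0. A difference by genotype cannot be told apart from chance between animals here, because the exact two-sided permutation within litters gave p = 0.0556, the smallest it can give with 2 against 2 in each litter. The count of 0 probe sets for genotype is matched by 35 of 35 splits of the 8 animals by construction (highest other 1) and tests nothing, while 32 of 35 splits gave at least the 1 list (highest other 13), the split by litter among them with 11 (the genotype count with litter as a block was 3), so chance cannot be excluded for the list. Of the 18 splits that part each litter evenly, as the genotypes do, 15 gave at least 1 list (highest other 12); what gives some splits several times the real count, a structure of the animals or the low preset correlation between list members, was not tested, and with an estimated correlation the genotypes gave 0 lists.

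Dim probe sets were slightly higher in S421A: the 4358 named probe sets in the lowest of 5 equal classes of mean level had a median difference of 0.04 (64.7% higher). The 4315 unnamed ones of the same level had a median of 0.04 (0.036), which met the bound set beforehand for array scale. After a further quantile normalization the named median was 0.0020, and without both animals numbered 4 it was −0.0031. However, in classes 3 to 5, the brighter ones, named medians were −0.010, −0.027 and −0.026 and unnamed ones 0.0078, 0.0090 and 0.0096. Named and unnamed rows did not shift alike there, so an effect of array scale is not settled. The difference of dim and bright probe sets per array did not pass an exact two-sided permutation test between the genotypes (p = 0.314). Olfactory and vomeronasal receptor genes, 1194 of which were measured, had a median of 0.05 at percentile 90.31 of random lists of the same level, which argues against a shift particular to these genes. No biological explanation was tested for this pattern.

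For 26 of 326 groups of 4 animals (7.98%, where chance gives about 5%, or 16.3 groups) 1 animal stood apart from the other 3. In WT animals these were Olfr60 (WT 4, 4.30) and Sgk1 (WT 3, 9.60). In S421A animals they were Palmd (S421A 3, 9.31), Trim30d (S421A 1, 4.24), Id3 (S421A 1, 7.19), Mt1 (S421A 3, 12.25) and Pvalb (S421A 4, 9.15). Within litter 1 they were Serpina3n (WT 1, 7.82), 1190005I06Rik (WT 2, 7.15), Olfr316 (S421A 1, 6.49), Junb (S421A 1, 8.18), Slc4a4 (S421A 2, 9.75), Ocln (WT 1, 7.38) and Rps20 (WT 1, 10.51). Within litter 2 they were Slc17a6 (WT 4, 10.15), Ndst4 (S421A 4, 6.66) and Tdo2 (WT 4, 6.22).

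Among means over lists, WT 4 stood apart for reported MeCP2 targets (8.88), blood within litter 2 (7.22), thalamus and striatum (7.83) and oxidative phosphorylation (10.58). S421A 4 stood apart for oxidative phosphorylation (10.58), S421A 3 for oligodendrocyte precursors (9.08) and WT 3 for the stress list within litter 2 (9.74). WT 4 also had the lowest mean array correlation of the WT animals (0.992), and S421A 4 the highest value of the S421A animals on principal component 1 (19.3).

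On the interaction term 4 lists passed with camera at the preset correlation, 7 on ranks, 0 with an estimated correlation (adjusted p = 0.691 for each) and 0 with fry. The S421A minus WT difference in litter 2 less that in litter 1 had a median of −0.14 for long neuronal genes, 0.13 for immediate early genes, −0.12 for meninges and −0.14 for MeCP2 cofactors, with 0 members of each past the threshold adjusted over the list alone. With quantile normalization 2 lists passed and without the dimmer probe sets 6, all of them higher, so long neuronal genes, meninges and MeCP2 cofactors lost their call under both settings. The count of 4 was 1 without WT 1, 1 without S421A 2, 8 without WT 2 and 9 without S421A 4.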

How the results depend on the processing

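Omitting both animals numbered 4, the hippocampus covariate, the block with an estimated correlation and all values for lists on the interaction term were chosen after the data had been seen. For genotype, 0 probe sets passed under every alternative run, within each litter, and without each animal in turn; the interaction likewise gave 0. The share of probe sets whose interval excluded 1.5-fold, 97.7%, ran from 83.6% (every probe set) to 98.6% (array weights). The 1 list for genotype became 3 with the litter block, 2 without the dimmer probe sets (adding meninges and oxidative phosphorylation, losing hippocampus), 4 on ranks, 2 without both animals numbered 4, and 0 with array weights, an estimated correlation, fry, or the block with an estimated correlation. With an animal left out it ran from 0 (without S421A 2) to 6 (without S421A 3), with 5 without WT 2, 4 without S421A 4 and 2 without WT 4. The block changed no other call. The 2 probe sets for litter became 0 with quantile normalization, median centring, 1 probe set per gene, every probe set, no genotype term, no animals numbered 4 or the hippocampus covariate, and 30 without the dimmer probe sets, 32 with trend and robust prior, 39 at an adjusted p of 0.1 and 93 (80 higher in litter 2) with array weights. With an animal left out it ran from 0 (without S421A 1, S421A 2, WT 2, S421A 4 or WT 4) to 26 (without WT 1). Testing more probe sets or fewer animals can itself change these counts; for the other settings the cause was not tested. The 10 lists for litter became 0 with an estimated correlation or fry, stayed between 8 and 11 elsewhere and ran from 7 to 11 with an animal left out. Their make-up changed, from 5 higher of 10 to 8 higher of 10 with array weights and 8 higher of 9 without both animals numbered 4. The 4 interaction lists (1 higher, 3 lower) became 2 with quantile normalization and 6 without the dimmer probe sets, all higher, so that the 3 lower lists lost their call under both. They became 7 on ranks and 0 with an estimated correlation or fry, and ran from 1 (without WT 1 or S421A 2) to 9 (without S421A 4), with 8 without WT 2. The microglia median for litter, −0.01, turned to 0.10 with array weights, 0.12 without both animals numbered 4 and 0.061 without S421A 4 (from −0.053 to 0.061 with an animal left out), where the list passed, and oxidative phosphorylation, −0.08, turned to 0.0036 without both; the cause was not tested. Of 2094 alternative values of named genes 1972 kept direction and side of the threshold, 23 lost and 70 gained a call, 0 called values reversed and 29 uncalled ones changed sign. Of 1614 list values 1330 kept both, 79 lost and 58 gained a call, 4 reversed (the microglia and oxidative phosphorylation values above) and 143 uncalled ones changed sign. Direction here is the sign of the median, and for microglia the test itself pointed up in the main litter fit too. The alternatives set for Mecp2 were not run. RMA compresses differences near background, where several genes named for genotype lay.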

Other observations

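In this part the genes Nts and Prox1 were chosen, and Tfrc and Trf set beside the blood markers, after their values were seen.

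Of the 15 entries of the blood list 6 were measured, and all 6 were lower in litter 2 (the list's adjusted p = 0.342 with an estimated correlation). The haemoglobin genes were not among them, so the amount of blood in the tissue cannot be read from this list. The transferrin receptor gene Tfrc differed by −0.62 (SE 0.11, adjusted p = 0.0860) and Trf, the transferrin gene in the oligodendrocyte list, by 0.39 (SE 0.08, adjusted p = 0.118), neither past the threshold over all probe sets. Trf measured 9.95 ± 0.07 in litter 1 and 10.34 ± 0.04 in litter 2 (SD, n = 4 each), with S421A minus WT at −0.04 and 0.05 within the litters. Of the clock genes Ciart was lower in litter 2 (9.15 ± 0.07 to 8.67 ± 0.10), and adjusted over the list alone it was the 1 member of 16 that fell.

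Nts, a neuropeptide gene, was 1.18 higher in litter 2 on the log2 scale (SE 0.21, adjusted p = 0.0860) and differed by −1.40 in litter 1 and −0.61 in litter 2 between S421A and WT. Prox1, a transcription factor gene of dentate granule cells that the interneuron list also holds, was 1.32 higher in litter 2. Both are values that did not pass over all probe sets.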
